A study of Escherichia coli with 5 samples.

How the data were processed

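ChIP-exo libraries of E. coli W were analysed: 1 untagged control, 2 WC and 2 WCm. The deposited files hold signal as whole-number read coverage per position and strand, not scaled to depth, with 1 file per library. Bowtie 1.2.2 and FastQC are named in the submitters' processing notes; mapping settings, filters and the treatment of duplicates are not given in the sources used here. Reads that map to repeated sequence, and PCR copies, could therefore raise or lower coverage at single positions. Positions in the files count from 0 and are printed here counting from 1, on the chromosome and 2 plasmids of E. coli W as the files name them. No genome sequence or annotation of these coordinates was used here, so genes were not named, gene lists fixed beforehand and the crp locus were not tested, and the CRP motif was not scored.

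Coverage on every replicon was a sum of reads of 32 bases, which allowed the read starts to be recovered. Coverage was summed over both strands in 50-bp windows. A window was called where it reached 4 times the local background, the median window within 5 kb on each side and not below the replicon median, and 2 times the control after each library was scaled to its replicon median. Called windows within 100 bp were joined, and a peak needed a called window in both libraries of a group. Overlap of at least 1 bp counted as shared. Peaks were shifted 1000 times along the chromosome to give a chance overlap.

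Signal in the union peaks was scaled to a total of 1000000 per library, and its log2 after adding a pseudocount of 1 was compared by limma 3.58.1 in R 4.3.3 with an intensity trend, WCm against WC, Benjamini-Hochberg adjustment over all 121 peaks, two-sided, threshold 0.05. Fold changes on this scale understate changes at low peaks. The control is a single library and stayed out of the fit. An exact permutation test of 2 against 2 libraries cannot go below 0.333 two-sided and was not used. Limma estimated 1 common curve of spread for all peaks, so small p-values rest on that assumption.

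Peaks were named by a rule set before the data were examined: the 10 with the highest enrichment over local background in WC, and the 10 with the largest log2 change in each direction past the threshold with both WCm libraries on the same side of both WC libraries. Borders were the positions with most 5-prime ends per strand within 100 bp of the highest window, with 1000 chromosome positions outside peaks as background. Stretches low in a group were sought after the data had been seen, as at least 10 windows of 1 kb in which the higher library of that group lay below 0.65 of the lower library of the other, joined within 3000 bp. A weaker limit, a ratio of group means below 0.8 with the same number of windows and joining, was also applied.

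The peak caller and the limma fit were tested on simulated data. The caller found 0% of simulated peaks of 2-fold height, 45% of 5-fold and 100% of 10-fold, with 0 calls elsewhere. The simulated control held random background without peaks, so this does not cover enrichment that a real control shares. For WCm against WC over 121 peaks, limma called 86% of changes of 0.5 on the log2 scale, 100% of changes of 1 and 1.73% of unchanged peaks. The simulated noise was normal, with the spread that limma had estimated from these data and no scaling shift. It therefore could not test the common curve of spread. Alternatives covered the thresholds, window size, control filter, overlap, scaling, pseudocount, trend, peak width, control subtraction, replicate block and each library left out. Added after seeing the data were scaling to the chromosome total, voom on recovered reads, a minimum log2 change of 1, the control scaled to its local background, and leaving out the low stretches. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.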

Results

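DNA bound by the cyclic AMP receptor protein CRP, a global transcription regulator of Escherichia coli, was mapped in strain W by ChIP-exo, in which an exonuclease trims immunoprecipitated DNA up to the cross-linked protein. The antibody recognised a myc epitope, carried as 8 copies on the tagged protein. The 5 libraries comprised 1 untagged control, 2 libraries titled WC and 2 titled WCm. The series names wild-type CRP and the mutant CRP(T168P), and WC was read here as the wild-type protein and WCm as the mutant. Per the labels, cells were induced at an optical density of about 0.9 for 6 h and cross-linked for 25 min, although names inside the files carry another time. The comparison of WCm with WC asks how binding of the mutant differs from that of the wild type. The groups also differed in stretches of low coverage and in plasmid depth, as described below. The amount of tagged protein and the yield of the precipitation were not measured here. A change in signal therefore cannot be assigned to the mutation by itself.

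Depth differed between libraries. The coverage corresponded to 5538758 reads in the untagged control, 8245020 and 7601528 in the WC libraries, and 4026667 and 7564306 in the WCm libraries. Mean chromosome coverage was 33.4 in the control, 40.5 and 37.3 in WC, and 20.9 and 39.3 in WCm. Reads in 1-kb windows on the log2 scale correlated across windows at 0.978 within WC and 0.978 within WCm, and at 0.695 to 0.722 between the groups. Without the 72 windows overlapping the stretches low in one group, left out after seeing the data, these values were 0.975, 0.972 and 0.942 to 0.952. With all windows included, the control correlated with the tagged libraries at 0.367 to 0.453. Windows are not independent replicates. Libraries of a group were not identical, with a chi-square per degree of freedom over these windows of 4.91 in WC and 3.49 in WCm, but PCR copies or library preparation also raise this value. Each was counted as a sample because the labels list it as one. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples.

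In WC 92 peaks were called and in WCm 88. The strongest WC peak, at chromosome positions 3690101 to 3690600, stood at 36.1 ± 3.75 times local background in WC (SD, n = 2) and 45.1 ± 4.15 times in WCm (SD, n = 2), against 2.60 times in the control. Next came 3457051 to 3457100, with 18.3 ± 1.17 times in WC and 22.02 ± 0.478 times in WCm (SD, n = 2), although the control also rose there, to 5.96 times. The peak at 328451 to 328650 reached 13.5 ± 1.14 times in WC and 12.9 ± 1.51 times in WCm (SD, n = 2), against 3.71 times in the control. The others among the 10 strongest WC peaks lay at 3974651 to 3975350, 2401201 to 2401300, 2772651 to 2772850, 45101 to 45550, 3923201 to 3923650, 3486501 to 3486700 and 2435401 to 2435600. Of these, the control reached 3.19 times at 3486501 to 3486700, 3.82 times at 2435401 to 2435600 and 1.17 to 1.97 times at the rest. No gene is named, because no annotation of these coordinates was used here.

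Most peaks were modest. The median enrichment over local background was 4.94 times in WC and 5.10 times in WCm. At WC peaks the signal was a median 2.46 times that of the control, and at WCm peaks 2.26 times. Single peaks ran from 1.32 to 28.6 times in WC and from 1.67 to 15.6 times in WCm. Calling required 2 times the control per window, so these medians follow in part from the filter. They also compare whole-library signal, and the chromosome held 92.3% of control reads, 75.1% in WC and 79.6% in WCm. The union of both sets held 121 peaks, of which 114 lay on the chromosome, 6 on the larger plasmid and 1 on the smaller plasmid. Union peaks held 0.954% of all signal in the control, 2.66% and 2.87% in the WC libraries, and 2.91% and 2.85% in the WCm libraries. These shares include plasmid peaks, and plasmids were covered more deeply in the tagged libraries. Chromosome peaks held 0.877% of chromosome signal in the control, 2.13% and 2.30% in WC, and 2.56% and 2.42% in WCm. The chromosome shares include peaks in a stretch low in WC, described below. Peaks were chosen for high signal in tagged libraries, which by itself favours larger shares there than in the control. The counts depended on the threshold: at an enrichment of 8 they were 10 in WC and 6 in WCm, and at 3 they were 243 and 195. With replicate 2 left out they were 104 and 167, and with replicate 1 left out 170 and 121.

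Of the 92 WC peaks, 57 were also called in WCm, a share of 62.0% (Wilson 95% interval 51.7% to 71.2%, counting error only). WC peaks of the chromosome, shifted along it, overlapped WCm peaks at a mean of 0.723% and at most 5.81% over 1000 shifts. Plasmid peaks were not shifted, whereas the 62.0% also counts WC peaks on plasmids. By the 4-fold rule without the control filter, the untagged control itself gave 389 peaks, and single tagged libraries gave 145 to 208. Overlap above the shifted value therefore does not by itself show that shared peaks are CRP binding. Both sets were filtered against 1 control library, and without that filter the share was 63.1%. It was 50.0% at an enrichment of 8, 60.6% without replicate 2 and 47.6% without replicate 1. Peaks called in a single group were not thereby shown to differ. Of 34 union peaks called only in WC, 18 were lower in WCm by the signal test. Of 29 called only in WCm, 21 were higher, including the 3 in the stretch low in WC described below. In each set 0 peaks passed in the other direction. The peaks were sorted with the same libraries that the test used, which favoured that direction in advance. The test is therefore no independent check of the sorting. These calls used signal scaled to the whole library. Over all union peaks, 14 higher and 20 lower calls held under all 4 scalings.

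Signal, scaled to a total of 1000000 per library, was higher in WCm than in WC at 36 of the 121 union peaks and lower at 22, by limma with Benjamini-Hochberg adjustment at 0.05. Outside the region described in the next paragraph, the highest rise was at 3974651 to 3975350, with a scaled signal of 555 ± 29.9 in WC and 2044 ± 104 in WCm (SD, n = 2), a 3.68-fold difference, against 131 in the control. The log2 change there was 1.88 (SE 0.11, limma adjusted p = 5.64e-42). Further rises were found at 1611901 to 1612000 with a log2 change of 1.47, at 2435401 to 2435600 with 1.22 and at 4813901 to 4814000 with 0.97. The control was itself enriched 3.82 times at 2435401 to 2435600 and 4.73 times at 4813901 to 4814000. Smaller rises lay at 2805901 to 2805950 with 0.88, at 4340651 to 4340700 with 0.62 and at 1330251 to 1330350 with 0.61. The peak at 4340651 to 4340700 lay within 5 kb of a stretch from 4342001 to 4353000 where WC coverage was a median 0.612 of WCm, and all 3 union peaks within 5 kb of that stretch were higher in WCm. The split of higher and lower calls depended on scaling: it was 16 and 23 when scaled to the median window outside peaks, 19 and 22 with the trimmed mean of M values and 23 and 24 when scaled to the chromosome total. Plasmids held 24.9% of reads in WC and 20.4% in WCm, so scaling to the whole library adds about 0.08 to log2 changes relative to chromosome scaling. The tested set includes 7 peaks on plasmids, and no scaling used here corrects for the depth of each plasmid. Relative to the chromosome, mean depth of the larger plasmid was 8.26 in WC and 6.59 in WCm. For the smaller plasmid it was 144.5 and 107.7. Changes at plasmid peaks therefore cannot be told apart from plasmid depth. The higher count was 17 without WC replicate 1, 10 without WCm replicate 1 and 18 without WCm replicate 2, where the lone library is assumed to vary like the others.

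The 3 peaks with the largest log2 changes were 2329001 to 2329600, 2329751 to 2330200 and 2328601 to 2328850. Their WCm signal was 354 ± 6.27, 274 ± 10.1 and 163 ± 31.1 (SD, n = 2), against 140, 120 and 91.4 in the control. WC signal was 0.461 ± 0.548 and 0.462 ± 0.0907 at the first and second (SD, n = 2), and both WC libraries held no coverage at the third. No fold is given, because it would depend on the pseudocount. These peaks lay in a chromosome region from 2306701 to 2337700 where WC coverage was 0.184 and 0.178 of the library median, against 1.27 and 1.23 in WCm and 1.19 in the control. Without such regions, 33 peaks were higher and 22 lower.

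Loss of signal in WCm was deepest at 2401201 to 2401300, with a scaled signal of 127 ± 13.7 in WC and 17.2 ± 1.62 in WCm (SD, n = 2), against 24.7 in the control. The log2 change was -2.82 (SE 0.15, limma adjusted p = 3.36e-48), and enrichment over local background was 10.7 ± 0.885 times in WC and 1.34 ± 0.0226 times in WCm (SD, n = 2). At 4877601 to 4877700 the log2 change was -1.96, with a scaled signal of 64.1 ± 4.24 in WC and 15.7 ± 1.003 in WCm (SD, n = 2), against 16.8 in the control. The other lower peaks named by the rule had log2 changes of -1.66 at 4540901 to 4540950, -1.61 at 3306701 to 3306850, -1.46 at 3802351 to 3802550, -1.44 at 4588201 to 4588300, -1.29 at 477101 to 477250, -1.28 at 508101 to 508200, -1.12 at 45101 to 45550 and -1.09 at 2136601 to 2136800. The peak at 45101 to 45550 was called in both groups, and the others here were called in WC only.

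Calls held under all 4 scalings, with the same sign, at 14 higher and 20 lower peaks, and 11 of the higher ones lay outside the stretch low in WC. Among the strongest WC peaks, 2772651 to 2772850 had a log2 change of -0.71 and 3923201 to 3923650 of -0.30, both lower by limma. The peak at 3457051 to 3457100 had a log2 change of 0.36 (limma adjusted p = 0.0105), with an SE of 0.12. It no longer passed at 0.27 (SE 0.14) with median window scaling, 0.27 (SE 0.12) with chromosome scaling, 0.50 (SE 0.18) after control subtraction, 0.31 (SE 0.15) without WC replicate 1, 0.39 (SE 0.13) without WCm replicate 1 and 0.32 (SE 0.13) without WCm replicate 2, so the change was larger, with a larger SE, in some of these. The call at 3923201 to 3923650 ended with any single library left out, at log2 changes from -0.39 to -0.21, and, at an unchanged -0.30 with a larger SE, with the replicate block and without the intensity trend. That at 1330251 to 1330350 ended without WCm replicate 1, at 0.53 (SE 0.16). The peaks at 3690101 to 3690600, 3486501 to 3486700 and 328451 to 328650 did not pass, with log2 changes of 0.12, 0.05 and -0.02, and the sign at 3486501 to 3486700 and at 328451 to 328650 turned under some settings. The trimmed mean of M values moved the median log2 change of all peaks by -0.103, from 0.14 to 0.04.

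**Figure D1:**
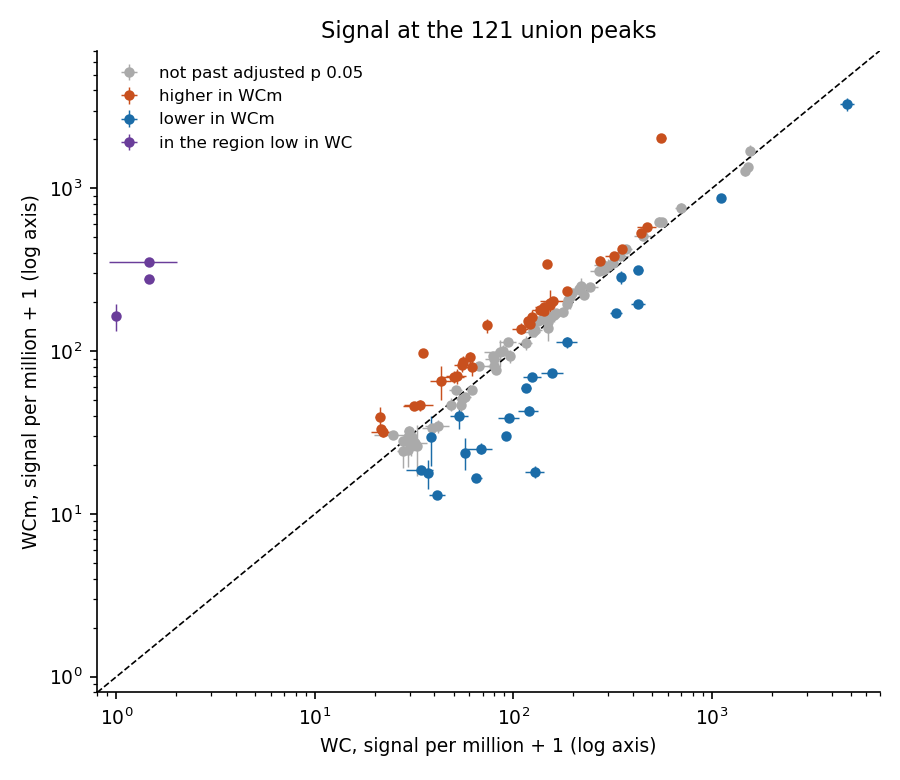
Library-scaled signal, with a pseudocount of 1 added, at the 121 union peaks in WC (x, log axis) and WCm (y, log axis); points are means of 2 libraries, bars their SD, and the dashed line marks equality. The 3 peaks at the left edge lie in the region from 2306701 to 2337700, low in WC.

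**Figure D2:**
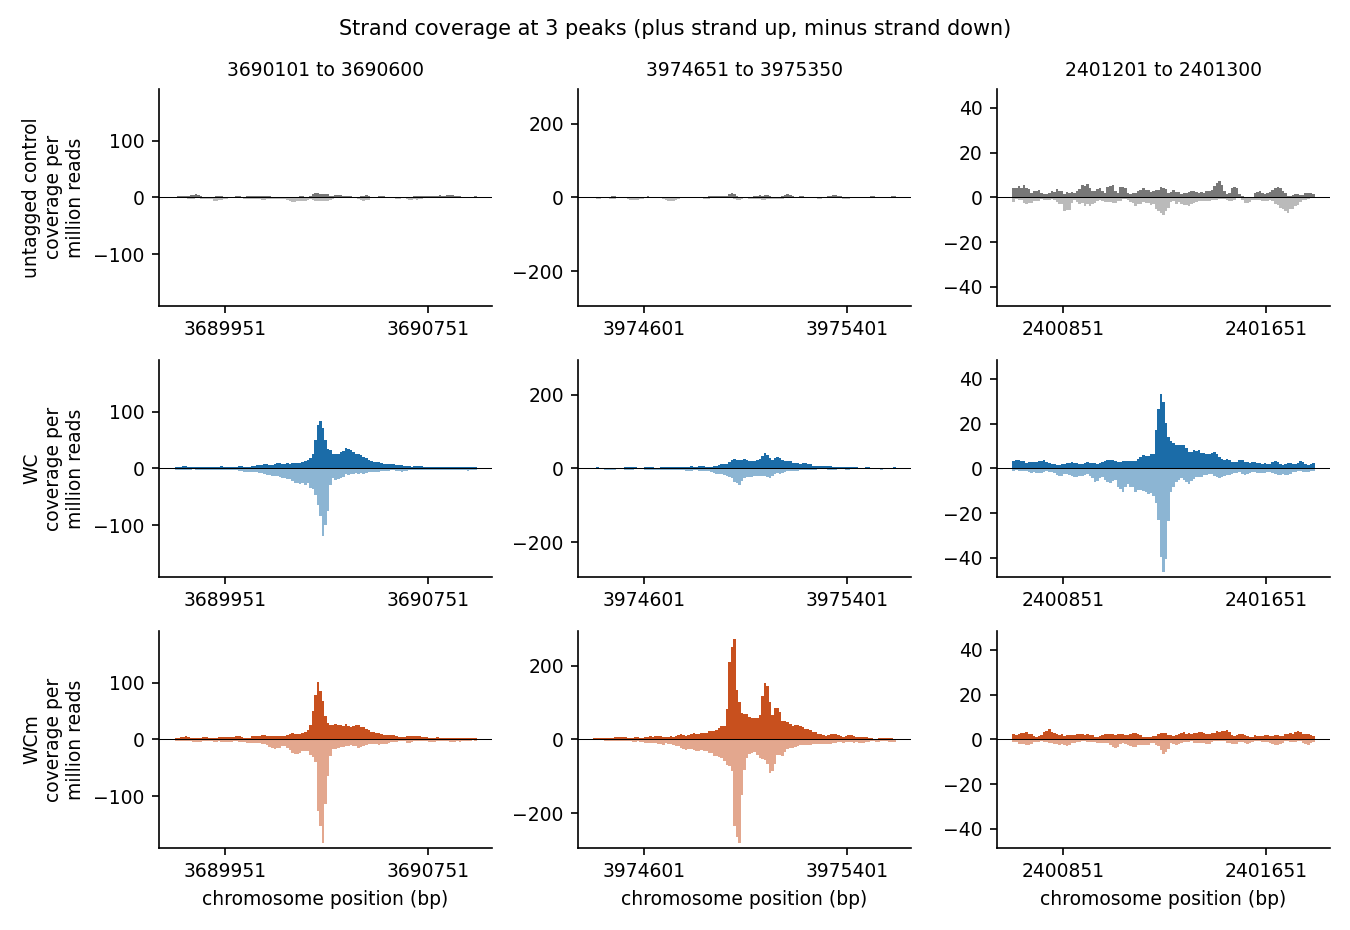
Coverage per 1000000 reads in 10-bp bins around 3 peaks (columns, chromosome positions in bp) in the untagged control, the mean of 2 WC libraries and the mean of 2 WCm libraries, with the plus strand upward and the minus strand downward. The first peak is present in both tagged groups, the second is higher in WCm, and the third is seen in WC.

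Borders were read from the 5-prime ends on each strand. The position with most minus-strand ends lay a median 31 bp downstream of the plus-strand position in both WC libraries, and 20 and 31 bp in the WCm libraries. This distance fell between 0 and 60 bp at 51.6 ± 0.769% of WC peaks and 43.7 ± 1.63% of WCm peaks (SD, n = 2). The share was 24.0% to 28.1% at chromosome positions outside peaks. Those positions were drawn at random, whereas peaks were centred on their highest window, so the background is not matched. How far the choice of centre raises the share at peaks was not tested. Plus-strand and minus-strand reads of 32 bases that cover the same bases also have 5-prime ends 31 bp apart, inside this range. Whether the median of 31 bp marks the edges of protected DNA or such reads was not tested. At 3457051 to 3457100 the borders were 3457056 and 3457105 in both groups, 49 bp apart, but the control was itself enriched 5.96 times there. At 3690101 to 3690600, the strongest WC peak, the distance was 59 bp in WC and 41 bp in WCm. At 3974651 to 3975350, the most enriched WCm peak, it was -81 bp in WC and 54 bp in WCm. The quartiles ran from -43.5 to 49.5 bp in WC replicate 1, so single peaks were poorly resolved. With centroids in place of maxima the median distance was -1.66 bp in WC and 1.71 bp in WCm. The share between 0 and 60 bp was then 43.5% and 44.6% in the WC libraries, below the 49.8% and 48.9% outside peaks, and 63.2% and 54.02% in the WCm libraries, against 50.7% and 49.1%. The border distances of both groups therefore rest on the maxima.

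WC and WCm each lacked most reads over a different stretch of the chromosome. WCm coverage from 2618101 to 2657900, a length of 39800 bp, was 0.0119 and 0.00296 of the library median, against 1.58 and 1.66 in WC and 1.44 in the control. The WCm libraries held 207 and 79 reads there. In WC the low stretch was the 31000 bp from 2306701 to 2337700, where 6213 and 5320 reads remained. The remaining WC coverage was uneven, with no reads at 41.2% and 43.6% of positions. In 1-kb windows from 2307001 to 2338000 the WC to WCm ratio ran from 0.00141 to 0.470. No union peak lay in the WCm stretch, and 3 lay in the WC stretch.

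**Figure D3:**
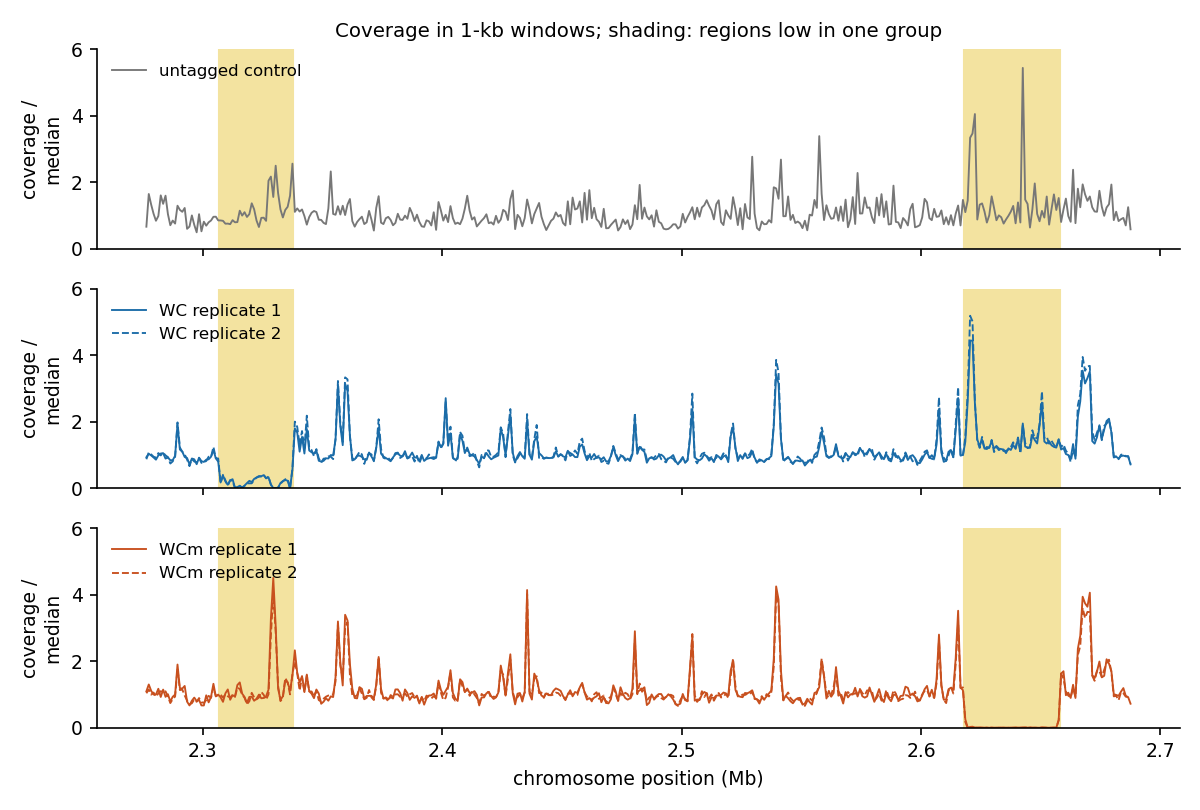
Coverage of 1-kb windows divided by the library median (y) along the chromosome in Mb (x) for the untagged control, 2 WC libraries and 2 WCm libraries. Shading marks 2306701 to 2337700, low in WC, and 2618101 to 2657900, nearly empty in WCm.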

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

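All tests in this part were chosen after the results were seen. Plasmid depth relative to the chromosome, which no comparison above tests, stood above the control, although plasmid reads enter the library totals and 7 union peaks lie on plasmids. The smaller plasmid was covered 143.0 and 146.0 times as deeply as the chromosome in the WC libraries and 107.8 and 107.7 times in the WCm libraries, against 9.83 times in the control. The larger plasmid was covered 8.30 and 8.21 times as deeply in WC and 6.62 and 6.57 times in WCm, against 3.45 times in the control.

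For the smaller plasmid, reads from a molecule sharing part of its sequence are argued against by the lowest decile of its 100-bp windows, which stood at 5.46 times the control in the lower group. Local protein binding is argued against by the median window, 11.6 times the control in the lower group. More copies of both plasmids in the tagged cultures stay open: the median window of the larger plasmid was 2.53 times the control in WC and 2.05 times in WCm, with 95.02% and 89.0% of windows above the control. The lowest decile there, 1.27 in WC and 0.968 in WCm, decides nothing, since chromosome windows in WCm also spread to a lowest decile of 0.492 of their median. More copies of the smaller plasmid by itself, whose lowest decile was 6.62 times the control in the higher group, stay open too, and with 1 control library neither can be told apart from a property of that library.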

How the results depend on the processing

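Peak counts in WC and WCm were 243 and 195 at an enrichment of 3, 10 and 6 at 8, 48 and 55 in 100-bp windows, and with a replicate left out ran from 104 to 170 and from 121 to 167. The shared percentage was 50.0 at an enrichment of 8 and ran from 47.6 to 60.6 with a replicate left out. Peaks higher in WCm numbered 16 with median window scaling, 19 with the trimmed mean of M values, 19 in the upper part by mean signal (7 lower), 4 at an enrichment of 8 (5 lower), 18 in fixed 200-bp windows and 23 after control subtraction. They ran from 10 to 31 with each library left out, and lower peaks from 16 to 24. Of the alternatives added after seeing the data, chromosome scaling gave 23 higher, and a minimum log2 change of 1 gave 6 higher and 11 lower. The centroid border distance was -1.66 bp in WC, reversed in sign, and 1.71 bp in WCm. Fewer peaks were tested in the upper part and at an enrichment of 8. The log2 ratio of chromosome read shares, 0.0838, accounts for the shift of -0.0835 in the median change with chromosome scaling; otherwise the cause was not tested. The replicate block gave 27 higher and 20 lower; deviations of same-numbered libraries correlated at -0.0758, and 2 pairs do not show pairing. Of 375 alternatives at 26 named peaks, 355 kept direction and side of the threshold, 13 lost the call and 7 turned sign at peaks without a call. At 3486501 to 3486700 the log2 change turned to -0.0341 with median window scaling, -0.0521 with the trimmed mean of M values and -0.0322 with chromosome scaling, and ran from -0.0424 to 0.145 with each library left out. At 328451 to 328650 it ran from -0.0774 to 0.0285 with each library left out. The listed promoters were not run. The caller found 45% of simulated 5-fold peaks, which limits weak peaks.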

Other observations

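All tests in this part were chosen after the results were seen. The 3 peaks between 2328601 and 2330200 were present in WCm and nearly empty in WC. A depth or scaling difference is argued against by 1-kb windows 50 to 100 kb away, with a median WC to WCm ratio of 0.991. Stronger binding in WCm by itself, with the sequence present in both, is argued against by windows outside peaks within 5 kb, where WC stood at a median 0.226 of the untagged control. The control did not enter the choice of the stretch low in WC. A candidate explanation is that the sequence was missing from most of the WC DNA. The median WC to WCm ratio in those windows was 0.277, with a range from 0.0175 to 0.426. It cannot decide the question, because those windows lie in the stretch that was chosen for a low WC to WCm ratio. Why the remaining WC coverage was uneven was not tested. Whether CRP(T168P) binds there differently cannot be read from these libraries.

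Large-scale coverage of the control peaked at 4.04 Mb with a fitted peak to trough ratio of 1.47, while tagged libraries gave 1.13 to 1.15 with peaks at 1.84 to 2.06 Mb. The lower depth of the control is argued against by WCm replicate 1, which had fewer reads and a ratio of 1.15. More ongoing chromosome replication in the untagged culture stays open. The log2 ratio of control to tagged coverage correlated with distance at -0.865 and -0.965 over the bins of both arms, but the distance was measured from the control's own maximum, so these values restate the pattern. Base composition was not tested, and the control was 1 library. The control filter of the peak caller scaled libraries to the replicon median, so it was stricter where the control was relatively high. With the control scaled to its local background instead, 103 peaks were called in WC and 86 in WCm. The share of WC peaks also called in WCm was then 61.2%.

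By the weaker limit of 0.8, WC coverage was lower than WCm over 4342001 to 4353000, with a median ratio of 0.612 and a highest of 0.761 in 11 windows. A search for the tag insertion, as chromosome boundaries crossed by at least 4 control reads and by no tagged read, found 0 among 1330 boundaries without tagged reads.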
